A study of Mus musculus with 4 samples.

How the data were processed

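Gene expression was measured by droplet single-cell RNA sequencing (Chromium 3' chemistry, version 3.1) in 4 libraries, 1 per group, of pooled mouse melanomas: WT control, WT treated, KO control and KO treated. The study's texts disagree on the number of control tumors per pool (3 in the design text, 2 in the protocol text; 5 treated tumors in both), so no value here uses it. The files deposited by the authors hold unnormalised UMI counts per gene and barcode for 31053 genes; the submitters' processing notes name Cell Ranger 5.0.0 and mm10, without saying what each was used for. Every deposited barcode holds at least 500 UMIs (lowest 501, 500, 500 and 500 in the order above), so empty droplets could not be examined. Median UMIs per deposited barcode were 6047, 7335, 1581 and 1064.

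Cells with at least 300 genes and at most 15% mitochondrial UMIs passed the filter (3329, 649, 11112 and 5205). Below the gene limit lay 720, 332, 964 and 793 barcodes, and above the mitochondrial limit 341, 53, 234 and 63. Scrublet doublet scores were computed per library, and the top-scoring cells were removed at 0.8% per 1000 barcodes (115, 5, 1090 and 252 cells). The kept cells were log-normalised, and 2000 variable genes, 30 principal components, 15 exact nearest neighbours and Leiden clustering at resolution 1.0 gave 27 clusters of the 4 libraries together. No batch correction was made, since library and group are the same. The random seed was 7.

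Clusters were named from 25 marker sets. A name needed at least 3 markers and a score of at least 0.3. Among the 10 leading genes, no other class could have more markers than the named one. A cluster far shallower than its libraries also took no name if none of its own markers was among these genes. A cluster needed 50% globin UMIs to be called erythroid. The marker sets, the 30 gene lists, the 4 comparisons, the rule for named genes and the first group of alternative settings below were fixed before the data were examined. The naming rule was not: it was revised 4 times after cluster tables had been seen, and the genes left out of the variable set were chosen after a first clustering. In its last form, clusters led by innate lymphoid type 2 markers count as T, plasma cells as B and lymphatic endothelium as endothelial, so T-like cells include innate lymphoid cells. Names therefore carry the ending "-like".

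The leading genes were as follows. T-like clusters were 2 (Cd8b1, Cd3g), 3 (Ifit1, Cd8b1), 5 (S1pr1, Il7r), 6 (Ikzf2, Tnfrsf4, Areg), 8 (Tnfsf11, Rora, Il17a), 12 (Stmn1, Top2a), 14 (Tnfrsf4, Ctla4) and 15 (Cd8b1, Ccl5). NK-like clusters were 7 (Gzma, Gzmc) and 19 (Gzma, Xcl1), and macrophage-like clusters 9 (Lyz2, Cd14) and 22 (Lyz2, C1qb). Dendritic clusters were 16 (Fscn1, Ccr7; migratory), 17 (Cd209a; cDC2), 18 (Siglech; plasmacytoid) and 21 (Naaa; cDC1). The others were 0 (S100a9; neutrophil), 24 and 25 (Igkc; B), 26 (Mcpt2; mast cell and basophil), 4 (Plvap; endothelial), 20 (Acta1; skeletal muscle) and 23 (Dcn; fibroblast). Clusters 1 (Macf1, Malat1), 10 (Ccl3, Ccl4, Il6), 11 (Mgp, Sparc) and 13 (Spp1, Mgp, Col3a1) took no name. A cluster that lies mostly in 1 library may be that library rather than a type, as cluster 13 does. Genes that lead a cluster describe how the cells were grouped.

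With 1 library per group, no test between groups, p-value or count of changed genes was made; cells were not used as replicates. The 4 comparisons were treated over control in WT and in KO, and KO over WT in control and in treated. Shares have exact Clopper-Pearson 95% intervals, and differences of shares Newcombe intervals. Where 0 cells were seen, the share allowed is 3 counts of the total. For each class with at least 50 cells in both libraries, UMIs were summed over cells and scaled to CPM, with exact Poisson intervals and an exact conditional interval on the log2 ratio; a fold against 0 is a lower bound from a floor of 3 counts over the class. All intervals cover counting error only, and those on CPM and its ratios treat UMIs of the same cell as independent.

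Named genes follow a fixed rule: the genes with the largest ratio in each direction by the bound of the interval nearer 0, 3 per side in T-like cells, 5 in macrophage-like cells and 2 in other classes. A gene had to reach 100 CPM and 20 UMIs in the higher library and 10% of its highest class value there, which limits free RNA from other cells. Mitochondrial, ribosomal protein, hemoglobin, immunoglobulin and T cell receptor segment genes, numbered gene models, Xist and Y-linked genes were left out. From each list, a few of its most abundant members are named as well. Some genes that these rules select are not reported here. Each gene list has the median log2 ratio of members with at least 20 UMIs, members at 0 in a library being set to the floor, with an interval from 1000 Poisson resamples and its percentile among 10000 random lists matched in 20 expression bins. A member counts as higher or lower at 1.5-fold or more. Which classes and lists are reported, and the 3 lists whose drug ratios are compared between genotypes, were picked after the list tables had been seen. The lists missed the symbols Ifi30, Mx2 and Cd244a.

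Shares of cells with a UMI were computed on all cells and after thinning each cell to 1000 UMIs, leaving out shallower cells. The planned results in melanoma cells (MAPK output and Gsdme in a melanoma class) have no value, because no cluster took that name; Gsdme is given for all cells, T-like cells and clusters 11 and 13 instead. The MAPK output list is reported for cluster 11 and some named classes, a choice made after the data had been seen.

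The first group of alternative settings were a looser filter (200 genes, 25% mitochondrial), a stricter filter (500 genes, 10%), doublets kept, resolutions 0.5 and 2.0, clustering of each library separately, naming each cell by its own scores, and thinning before clustering. Further ones were TMM scaling of class sums, subtraction of 5% of the library profile, no UMI minimum on list members, and all kept cells as denominator. Innate lymphoid markers kept apart from T, no minimum score for a name, and cells of at least 2000 UMIs were added after the data had been seen.

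The calculation of intervals and lists was checked on simulated counts, drawn as Poisson counts from whole-library profiles. In the 4 comparisons, intervals covered the true ratio for 95.7%, 95.5%, 95.5% and 95.5% of genes. Newcombe intervals covered the true difference in 95.6%, 95.0%, 95.4% and 96.6% of binomial draws at fixed shares not taken from the libraries. Such draws follow the model that the intervals assume, so they do not test how UMIs clump within cells. Gene positions came from the mm10 annotation, which placed 30934 genes (99.6%). The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, statsmodels 0.14.6, igraph 0.11.9 and matplotlib 3.10.9.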

Results

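Single-cell RNA sequencing was carried out on mouse melanomas that differed in tumor genotype and in diet. The tumors grew from YUMM1.7 cells, a transplantable melanoma line of C57BL/6 origin, injected into the skin of C57BL/6J mice. The cells were either unedited (WT) or knocked out for Gsdme (KO), which encodes gasdermin E, a pore-forming protein that caspase-3 cleaves in pyroptotic cell death. Mice with tumors of 100 to 200 mm3 ate chow with a BRAF inhibitor and a MEK inhibitor (treated) or vehicle chow (control), and tumors were taken on day 4. Tumors of a group were pooled, cleared of dead cells, sorted for cells without Annexin V staining, and loaded as 1 library per group. The 4 libraries held 4336 barcodes and 34579434 UMIs (WT control), 1029 barcodes and 8192560 UMIs (WT treated), 12257 barcodes and 42938874 UMIs (KO control), and 6053 barcodes and 13629491 UMIs (KO treated). After filtering, 3214, 644, 10022 and 4953 cells were kept, with median depths of 6458, 7711.5, 1725.5 and 1143 UMIs per cell in the same order. With 1 library per group, no difference below has a replicate check, and the 95% intervals given cover counting error only.

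The targeted gene was detected in all 4 libraries. Gsdme (ENSMUSG00000029821.15 in the annotation used, chromosome 6, 50188888 to 50263862, minus strand, mm10) gave 317 UMIs or 11.4 CPM (counts scaled to the same library total; interval 10.2 to 12.7) in WT control and 42 UMIs or 7.87 CPM (5.67 to 10.6) in WT treated. KO control had 227 UMIs or 6.18 CPM (5.40 to 7.04), and KO treated had 122 UMIs or 10.8 CPM (8.93 to 12.8). Host cells carried it, at 8.18, 7.05, 5.33 and 9.14 CPM in T-like cells of WT control, WT treated, KO control and KO treated. In the unnamed clusters it gave 95 UMIs (14.3 CPM, 11.5 to 17.4) in cluster 13 of WT control. In cluster 11 it gave 9 UMIs (19.6 CPM, 8.97 to 37.3) in WT control and 13 UMIs (11.3 CPM, 6.00 to 19.3) in KO control. No cluster took the melanoma name, and the pigment genes Mlana and Dct were near zero: over all kept cells of WT control, WT treated, KO control and KO treated, Mlana gave 2, 0, 0 and 17 UMIs and Dct gave 1, 0, 1 and 14. Other markers of that type, which host cells can also make, were seen: Mitf gave 287, 26, 98 and 65 UMIs and Ednrb 178, 89, 60 and 24 in the same order. Because the editing concerned only the injected cells and a 3' tag can lie outside an edited part, these Gsdme values check nothing about the labels.

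Most kept cells were leukocytes. Immune classes made up 84.8% of kept cells in WT control (2724 of 3214; 83.5 to 86.0%), 94.6% in WT treated (609 of 644; 92.5 to 96.2%), 94.0% in KO control (9418 of 10022; 93.5 to 94.4%) and 82.4% in KO treated (4082 of 4953; 81.3 to 83.5%). T-like cells were the most frequent class in all 4 libraries. The removal of dead and Annexin V-stained cells, the inclusion of every barcode down to 500 UMIs, and the gap in depth between the WT and KO libraries can all set such shares. Of the clusters that took no name, cluster 13 held 7.78% of the cells of WT control (250 of 3214; 6.88 to 8.76%), 0.07% of KO control (7 of 10022) and none in WT treated or KO treated, where 0 of 644 and 0 of 4953 cells allow shares of up to 0.466% and 0.061%. Cluster 13 scored nearest to fibroblast (0.245, below the 0.3 needed), so the fibroblast-like share of WT control depends on the naming rule. It was 0.12%, but 7.9% with no minimum score and 6.88% with cells named by their own scores. Cluster 11 held 2.77%, 0%, 3.23% and 2.32% of WT control, WT treated, KO control and KO treated cells, cluster 1 held 3.76%, 4.35%, 2.05% and 1.23%, and cluster 10 held 0.22%, 0.31%, 0.01% and 0.67%.

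**Figure D1:**
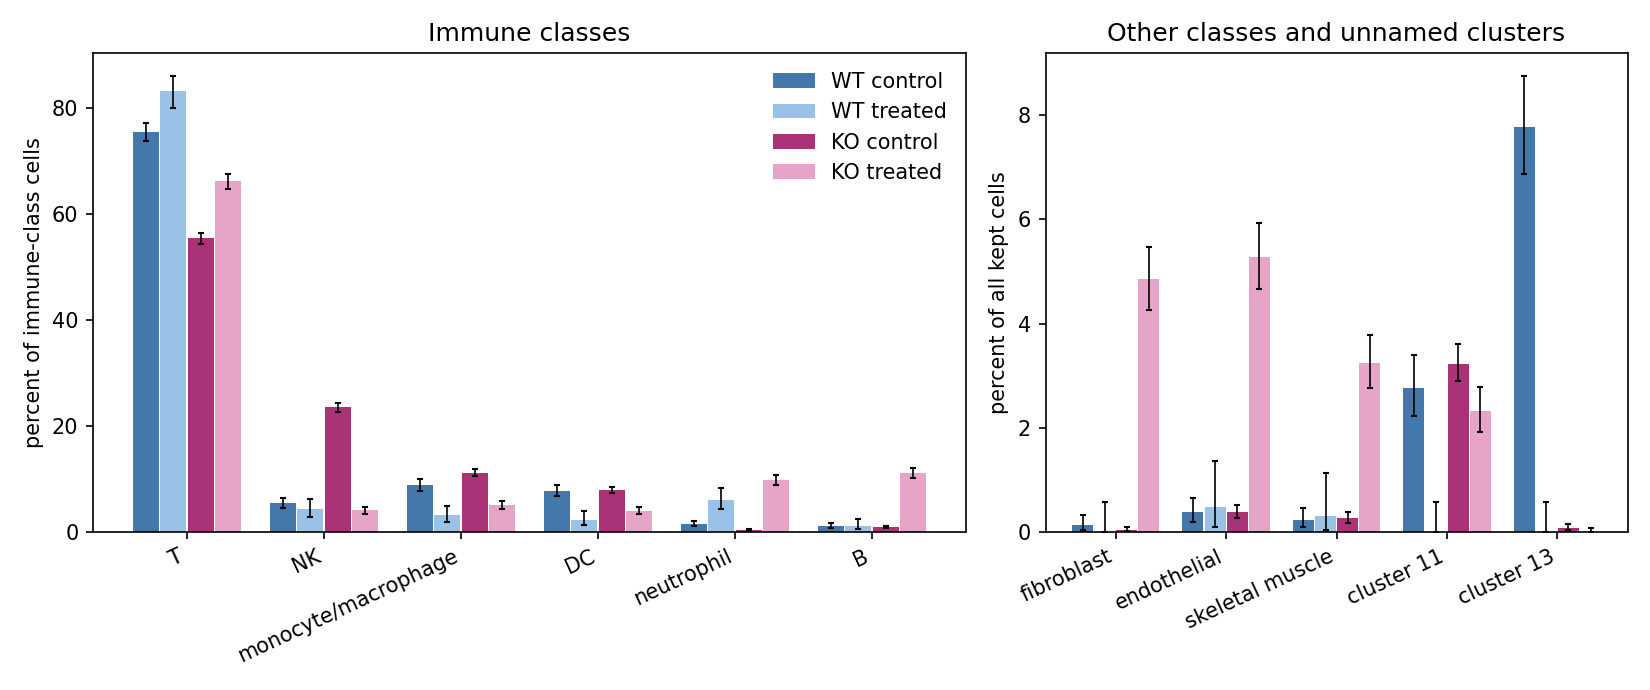
Share of cells per class in each library, with immune classes as percent of immune cells on the left and other classes and unnamed clusters as percent of all kept cells on the right. Bars are 1 library each and error bars are exact 95% binomial intervals; NK-like cells reach 23.5% in KO control, and fibroblast-like, endothelial-like and muscle-like cells reach 4.85%, 5.27% and 3.25% in KO treated.

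The first comparison asks what the drug chow did in tumors of unedited cells. The WT treated library held relatively more T-like cells and neutrophils and fewer macrophages and dendritic cells than WT control, and its T-like cells carried much less interferon-induced RNA. T-like cells were 83.1% of immune cells in WT treated (506 of 609) and 75.4% in WT control (2054 of 2724), a difference of 7.68 points (4.13 to 10.9), or 14.66 points of all kept cells. Monocyte/macrophage-like cells were 3.12% (19 of 609) against 8.81% (240 of 2724), a difference of -5.69 points (-7.27 to -3.71), or -8.78 with doublets kept. In T-like cells, 18 of 21 measured members of the type I interferon response list were at least 1.5-fold lower and none was higher, with a median log2 ratio of -1.71 (-1.80 to -1.50).

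Among other leukocytes, neutrophils were 6.08% of immune cells in WT treated and 1.51% in WT control (difference 4.57 points, 2.85 to 6.79). Dendritic cells were 2.30% against 7.75% (-5.45 points, -6.86 to -3.65, or -2.90 with doublets kept). The shortfall lay in conventional dendritic cells: cDC1-like cells, which cross-present antigen, were 3 of 609 against 72 of 2724, and cDC2-like cells, which prime CD4 T cells, were 0.33% against 3.30%. Migratory dendritic cells (1.31% and 1.21%), NK-like cells (4.27% and 5.36%; difference -1.09 points, -2.71 to 0.98) and B-like cells (1.15% and 1.10%) were not distinguishable at this depth. The immune share of all cells was 9.81 points higher in WT treated (7.45 to 11.8), and this total includes the absence of cluster 13 there.

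T-like cells were the only class with at least 50 cells in both WT libraries, and they lay in different clusters. Cluster 6 held 206 of 506 in WT treated and 1280 of 2054 in WT control, and cluster 15, led by Cd8b1 and Ccl5, held 128 and 176. By the naming rule, the RNAs lowest in WT treated relative to WT control began with Cxcl10, a chemokine that attracts CXCR3-bearing T cells, at 96.4 against 356 CPM (log2 ratio -1.88, -2.03 to -1.74). Next came Isg15, an interferon-induced ubiquitin-like modifier, at 114 against 406 CPM (-1.83, -1.96 to -1.70), and the virion tether Bst2 at 105 against 342 CPM (-1.71, -1.85 to -1.57). Among the highest were Klrc1 and Klrc2, which encode NKG2 receptors, at 208 against 79.0 CPM (1.40, 1.27 to 1.53) and 125 against 46.6 CPM (1.42, 1.25 to 1.59).

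The interferon list median lay at percentile 0 of 10000 random lists matched on expression. Its most abundant members included Ifi27l2a at 1179 against 2850 CPM. The interferon gamma response list had a smaller median of -0.49 (-0.61 to -0.44), with 7 of 18 members lower and none higher. Of 18 cytotoxic effector genes, 7 were higher and 4 lower, with a median of 0.35 (0.24 to 0.44; percentile 100): Nkg7, a granule protein, was at 835 against 496 CPM, Klrk1, the NKG2D receptor, at 272 against 149 CPM, and Gzmb, the protease granzyme B, went the other way at 534 against 1088 CPM. All 8 measured MHC class II genes were lower (median -1.10, -1.44 to -0.92), at levels led by Ctss at 183 against 306 CPM and Cd74 at 138.5 against 264 CPM. Macrophages and dendritic cells make far more of this RNA and had lower shares in WT treated. The median was -0.74 with 5% of the library profile subtracted, and inflammatory macrophage genes, too, were lower in T-like cells for 8 of 13 members (median -0.67, -0.86 to -0.47, or -0.13 with cells thinned to 1000 UMIs). Hypoxia and glycolysis genes were lower for 8 of 19 members (median -0.52, -0.58 to -0.46), and chemokines for 6 of 10 (median -0.73, -1.30 to -0.42, or 0.13 with each library clustered by itself). The former included Aldoa at 435 against 733 CPM and Pgk1 at 180 against 327 CPM.

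The regulatory T list had a median of -0.40 (-0.46 to -0.25) with 2 of 14 members lower and 1 higher, and Foxp3, the lineage factor of regulatory T cells, was found in 13.5% of WT treated and 17.4% of WT control T-like cells after thinning to 1000 UMIs (32.4% and 41.7% unthinned). In macrophage-like cells, which mostly lack it, the shares were 0% and 0.44% (0% and 5.00% unthinned). A Cd8a UMI was found in 12.4% and 4.81% of T-like cells (29.2% and 11.98% unthinned), against 0% of macrophage-like cells in both libraries (0% and 0.83% unthinned). Thinning left out 16 and 60 T-like and 0 and 11 macrophage-like cells, and the median depths were 8105.5 and 6020 UMIs in T-like and 14691 and 10117 UMIs in macrophage-like cells. Exhaustion and checkpoint genes had a median of -0.12 (-0.16 to -0.08), and naive and memory genes 0.36 (0.22 to 0.51), with Ly6c2 at 859 against 463 CPM and Klf2 at 252 against 564 CPM. G2M phase genes were lower for 15 of 20 members (median -1.04, -1.22 to -0.79), but with cells thinned to 1000 UMIs the median was -0.01; S phase genes had a median of -0.14 (-0.28 to -0.05). Dissociation stress genes were lower for 10 of 17 members (median -0.61, -0.66 to -0.53), and the pyroptosis and inflammasome list had a median of -0.20 (-0.46 to -0.13). Mitochondrially encoded genes, a check of RNA quality, had a median of 0.46 (0.44 to 0.47; percentile 100), with a median of 2.72% mitochondrial UMIs per T-like cell in WT treated and 1.81% in WT control. All 12 measured extracellular matrix genes, which T cells do not normally make, were lower (median -2.17, -2.40 to -1.84), with Col3a1 at 0 against 13.1 CPM and Sparc at 0 against 11.3 CPM.

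**Figure D2:**
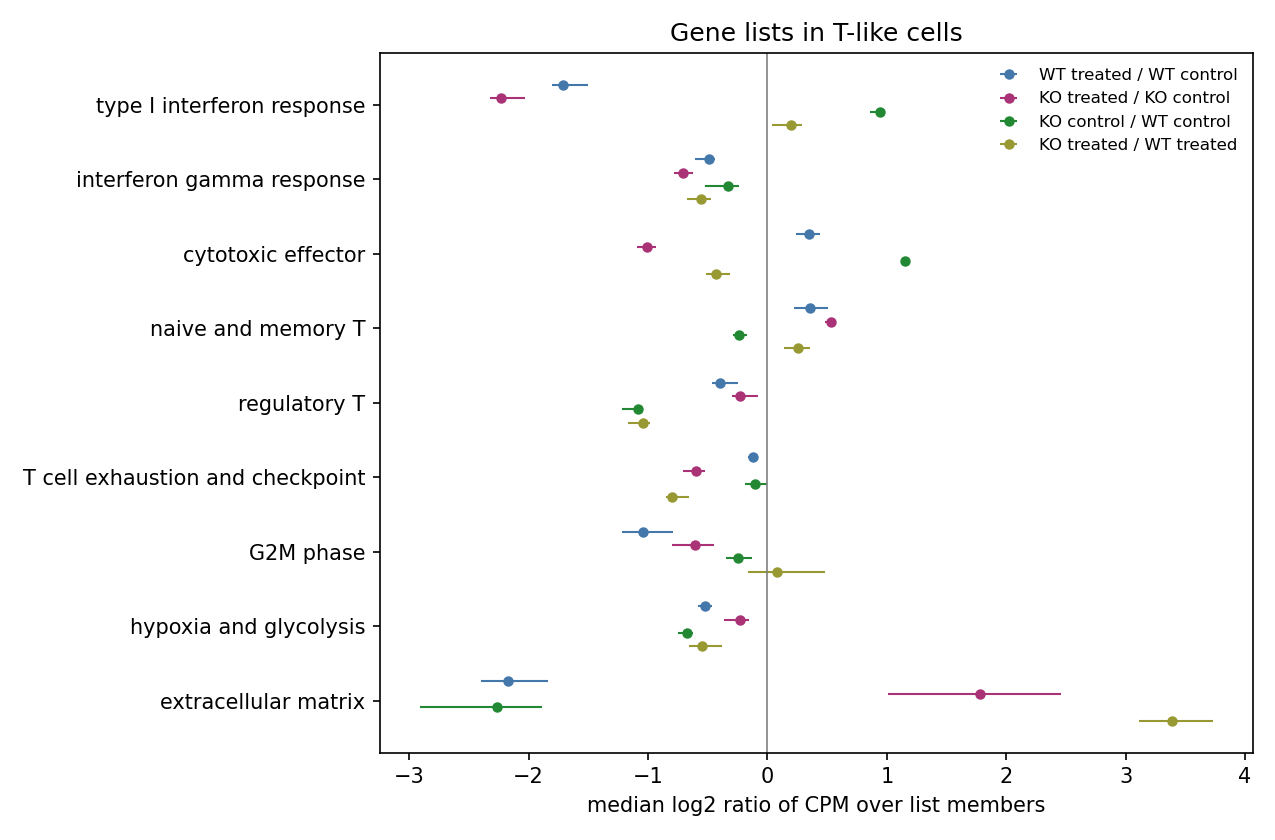
Median log2 ratio of CPM over the measured members of 9 gene lists in T-like cells, for the 4 pairs of libraries. Points are medians and bars are 95% intervals from Poisson resampling (counting error only); the type I interferon list lies at -1.71 and -2.23 in the treated over control pairs and at 0.94 for KO control over WT control, a pair that scaling by TMM moves up to 1.12.

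The second comparison asks the same question in tumors of Gsdme knockout cells. Relative to KO control, the KO treated library held far fewer NK-like cells and fewer macrophages, larger immune shares of T-like cells, B-like cells and neutrophils, and fibroblast-like, endothelial-like and muscle-like cells that were scarce in KO control. NK-like cells were 4.02% of immune cells in KO treated (164 of 4082) and 23.5% in KO control (2213 of 9418), a difference of -19.5 points (-20.5 to -18.4). Monocyte/macrophage-like cells were 5.02% (205 of 4082) against 11.1% (1049 of 9418), or -6.12 points (-7.02 to -5.17). Interferon-induced RNA was lower in T-like, NK-like and macrophage-like cells alike, with 20, 20 and 19 of 21 list members at least 1.5-fold lower.

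T-like cells were 66.1% of immune cells in KO treated (2697 of 4082) and 55.3% in KO control (5209 of 9418), a difference of 10.8 points (8.99 to 12.5) that turned to -3.92 with each library clustered by itself and was 2.48 points of all kept cells. B-like cells were 11.1% against 0.83% (10.3 points, 9.32 to 11.3). Neutrophils were 9.80% against 0.37% (9.43 points, 8.54 to 10.4), although only 1.45 points of this difference remained with the stricter filter (at least 500 genes and at most 10% mitochondrial UMIs). Dendritic cells were 3.94% against 7.90% (-3.96 points, -4.75 to -3.12), and cDC1-like cells were 1 of 4082 against 192 of 9418. Mast cells and basophils were 2 of 4082 against 90 of 9418. Of all kept cells, the immune share differed by -11.6 points (-12.7 to -10.4), beside 4.85% fibroblast-like cells against 3 of 10022, 5.27% endothelial-like cells against 0.38%, and 3.25% skeletal muscle-like cells against 0.26%. With cells named by their own marker scores, the differences were smaller for NK-like (-11.4 points), B-like (4.2 points) and dendritic cells (-0.33 points) and larger for macrophage-like cells (-9.49 points). The muscle-like difference of 2.99 points was 0.24 points with each library clustered by itself. The share of UMIs from globin genes was also higher in KO treated, at 7.23% against 1.90%.

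In T-like cells the largest ratio by the naming rule was that of Il17a (ENSMUSG00000025929), the cytokine of type 17 T cells, at 252 CPM in KO treated and 15.6 CPM in KO control (log2 ratio 4.02, 3.85 to 4.19). Its 1794 and 321 UMIs came from only 69 and 55 cells. The interval takes each UMI as independent, so it does not cover the sampling of these few cells. At 1000 UMIs per cell, 2.98% of KO treated and 0.84% of KO control T-like cells had an Il17a UMI (2.56% and 1.06% unthinned), against 0% of macrophage-like cells in both libraries. Thinning left out 1119 and 1421 T-like and 80 and 284 macrophage-like cells, and the median depths were 1195 and 2569 UMIs in T-like and 1297 and 1490 UMIs in macrophage-like cells. Ifitm1, an interferon-inducible membrane protein, was at 322 against 49.0 CPM (2.72, 2.61 to 2.83), and S1pr1, the receptor for lymphocyte exit from tissue, at 352 against 76.7 CPM (2.20, 2.11 to 2.29). The lowest were Rsad2, encoding viperin, at 13.4 against 146 CPM (-3.45, -3.76 to -3.15), and Hspa1a, an inducible heat shock protein, at 34.5 against 345 CPM (-3.32, -3.51 to -3.14). Ifit3, an antiviral effector, was at 25.3 against 198 CPM (-2.97, -3.19 to -2.75). Cluster 2, of low UMI counts and led by Cd8b1, held most T-like cells of KO treated (1374 of 2697), while clusters 2 and 15 held 1234 and 1170 of 5209 in KO control.

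The type I interferon list in T-like cells had a median of -2.23 (-2.32 to -2.03; percentile 0), with Ifi27l2a at 1326 against 3307 CPM, Isg15 at 191 against 781 CPM and Bst2 at 167 against 607 CPM. Of 19 cytotoxic effector genes, 17 were lower and 1 higher (median -1.01, -1.09 to -0.93; percentile 0): Nkg7 was at 652 against 1531 CPM and Gzmb at 316 against 924 CPM, while Ccl5, a chemokine of effector T cells, stood at 3920 against 3636 CPM. The NK-like share, whose cells carry the list too, fell in the same pair. So did the share of T-like cells with a Cd8a UMI. At 1000 UMIs it was 12.8% in KO treated and 26.98% in KO control (18.84% and 41.08% unthinned). In macrophage-like cells it was 2.40% and 7.45% (3.90% and 11.63% unthinned). Interferon gamma response genes were lower for 12 of 19 members (median -0.71, -0.78 to -0.62), and exhaustion and checkpoint genes for 7 of 14 (median -0.60, -0.71 to -0.52), among them Nr4a2 at 258 against 490 CPM. The naive and memory list was higher by its median (0.53, 0.48 to 0.57), with 4 of 12 members higher and Ly6c2 lower at 671 against 1832 CPM. Regulatory T genes had a median of -0.23 (-0.30 to -0.08; percentile 8.1), and MHC class II genes -0.12 (-0.36 to 0.13, or -0.72 with each library clustered by itself). Hypoxia and glycolysis genes had -0.23 (-0.36 to -0.15), dissociation stress genes -0.29 (-0.31 to -0.25) and mitochondrially encoded genes 0.12 (0.10 to 0.15). Chemokines had a median of 0.25 (0.07 to 0.54, or -2.5 with 5% of the library profile subtracted), with 5 of 13 members higher and 4 lower. The median of S phase genes was 0.00 (-0.12 to 0.08), as was that of pyroptosis and inflammasome genes (0.00, -0.23 to 0.10). G2M phase genes had a median of -0.61 (-0.80 to -0.45), which was 0.17 with cells thinned to 1000 UMIs. Extracellular matrix genes were higher for 8 of 11 members (median 1.78, 1.01 to 2.46), at low levels such as Sparc at 9.70 against 1.12 CPM; this moved with the fibroblast-like share of the library, and the median was 0.64 with 5% of the library profile subtracted.

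NK-like cells of KO treated lacked detectable Spp1, which encodes osteopontin: 0 UMIs against 3625 in KO control (496 CPM), at least 56.8-fold lower. Gzmc, a granzyme of activated killer cells, was at 64.0 against 1208 CPM (log2 ratio -4.24, -4.91 to -3.64). Nfkbid, an atypical inhibitor of NF-kappa-B, was at 186 against 31.0 CPM (2.58, 2.16 to 2.99), and the noncoding RNA Kcnq1ot1 at 393 against 89.3 CPM (2.14, 1.86 to 2.41). The type I interferon median in NK-like cells was -2.43 (-2.80 to -1.98), or -1.43 with cells thinned to 1000 UMIs, with Ifi27l2a at 166 against 522 CPM. MHC class I presentation genes had a median of -0.52 (-0.66 to -0.31), interferon gamma response genes -0.67 (-0.86 to -0.23), and pyroptosis and inflammasome genes -0.83 (-1.17 to 0.02). The cytotoxic effector list had a median of 0.11 (-0.23 to 0.30) over members that went both ways, with Ccl5 at 8494 against 2593 CPM and Gzma at 4762 against 3865 CPM. Cluster 19, of low UMI counts, held 126 of the 164 NK-like cells of KO treated and 1537 of 2213 in KO control.

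Monocyte/macrophage-like cells of KO treated carried less antigen-presentation RNA: all 10 measured MHC class II genes were lower, with a median of -1.68 (-1.83 to -1.48; percentile 0). Cd74, the invariant chain, was at 5317 against 15743 CPM, H2-Ab1 at 1539 against 7012 CPM and H2-Aa at 1731 against 6357 CPM. Type I interferon genes had a median of -1.52 (-1.81 to -1.36), with Isg15 at 303 against 1649 CPM and Irf7 at 185 against 548 CPM. Inflammatory macrophage genes were lower for 11 of 18 members (median -1.10, -1.28 to -0.66), including the cytokine gene Il1b at 956 against 3056 CPM and the neutrophil attractant Cxcl2 at 818 against 1836 CPM, and chemokines for 10 of 17 (median -1.17, -1.29 to -0.61); with cells named by their own marker scores these medians were -0.12 and -0.02. Lipid-laden macrophage genes had a median of -0.48 (-0.68 to -0.30), with Apoe, a lipid carrier, at 1676 against 7561 CPM. Hypoxia and glycolysis genes were lower for 12 of 18 members (median -0.73, -1.08 to -0.59). Cluster 22, of low UMI counts, held most of this class in both libraries (190 of 205 and 828 of 1049), and globin made up 10.99% of the UMIs of the class in KO treated and 1.14% in KO control. The median mitochondrial share per cell of the class was 0.96% in KO treated and 1.32% in KO control.

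By the naming rule, the macrophage RNAs highest in KO treated relative to KO control were Lyz1, a lysozyme, at 203 against 5.30 CPM (log2 ratio 5.25, 4.53 to 6.04), and the monocyte attractant Ccl8 at 428 against 36.7 CPM (3.54, 3.21 to 3.88). Then came Tnfrsf4, the costimulatory receptor OX40, at 398 against 54.3 CPM (2.87, 2.57 to 3.18), lipoprotein lipase Lpl at 120 against 19.7 CPM (2.61, 2.05 to 3.15), and Add3 at 113 against 28.5 CPM (1.98, 1.45 to 2.50). Tnfrsf4 is also a T cell gene, and T cell lists were higher in these cells too. Regulatory T genes were higher for 6 of 10 members (median 1.06, 0.59 to 1.36; percentile 100; 0.02 with cells named by their own scores) and naive and memory genes for 7 of 11 (1.06, 0.58 to 1.38; percentile 100). The lowest were Arg1, the arginase of suppressive macrophages, with 1 UMI against 644 (log2 ratio -6.10, -11.4 to -3.61), Spint1 with 0 UMIs against 397 (at least 14.1-fold lower), and Rsad2 at 20.02 against 373 CPM (-4.22, -5.43 to -3.24). Few UMIs were left of the endocytic adaptor Dab2, 2 against 624 (-5.05, -8.10 to -3.19), and of Spp1, 1 against 475 (-5.66, -10.96 to -3.17). MHC class I genes had a median of -0.18 (-0.39 to -0.14) and interferon gamma response genes -0.62 (-0.82 to -0.31). Alternatively activated and resident-like genes had -0.46 (-0.86 to 0.05), efferocytosis genes -0.34 (-0.96 to -0.07), and pyroptosis and inflammasome genes -0.27 (-0.53 to 0.01). The cytotoxic effector list, of genes macrophages do not normally make, had a median of -0.02 (-0.43 to 0.25).

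The third comparison asks whether tumors of knockout cells differed without drug. KO control held 4.38 times the NK-like share of WT control, a smaller share of T-like cells, and among its T-like cells more CD8 and cytotoxic RNA and less regulatory T cell RNA. NK-like cells were 23.5% of immune cells in KO control (2213 of 9418; 22.6 to 24.4%) and 5.36% in WT control (146 of 2724; 4.54 to 6.27%), a difference of 18.1 points (16.9 to 19.3). Most of this difference lay in cluster 19, of low UMI counts, with 1537 cells of KO control and 8 of WT control. Cluster 7 held 676 and 138 cells. T-like cells were 55.3% against 75.4%, or -20.1 points (-22.0 to -18.2). Interferon-induced RNA was higher in KO control in T-like, NK-like and macrophage-like cells, with 14, 21 and 15 of 21 list members at least 1.5-fold higher and none lower.

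The gap in depth between these libraries (medians of 1725.5 and 6458 UMIs) bears on every share. With cells of at least 2000 UMIs alone, NK-like cells were 18.8% against 5.94% and the T difference was -11.1 points; with cells named by their own marker scores the differences were 9.80 and -8.24 points. NK-like cells of both libraries carried Ncr1, the natural cytotoxicity receptor NKp46, in 16.2% (KO control) and 23.4% (WT control) of cells at 1000 UMIs, leaving out 727 and 1 shallower cells (31.8% and 70.5% unthinned, median depths 1422 and 7401 UMIs). T-like cells, which mostly lack it, did so in 0.53% and 0.15% (1.06% and 0.44% unthinned, median depths 2569 and 6020 UMIs, with 1421 and 60 left out). The T cell gene Cd3e was found in 12.2% and 1.38% of these NK-like cells at 1000 UMIs (18.9% and 2.05% unthinned), against 44.2% and 33.6% of T-like cells (67.7% and 78.7% unthinned). Monocyte/macrophage-like cells were 11.1% against 8.81% (2.33 points, 1.04 to 3.53), a difference that was 0.41 points among cells of at least 2000 UMIs and -0.93 with doublets kept. Neutrophils were 0.37% against 1.51% (-1.13 points, -1.67 to -0.71), and dendritic cells 7.90% against 7.75% (0.15 points, -1.03 to 1.25). Migratory dendritic cells were 2.72% against 1.21% (1.51 points, 0.93 to 2.00), and mast cells and basophils 0.96% against 2 of 2724. B-like cells, at 0.83% and 1.10%, were not distinguishable. The immune share was 9.22 points higher (7.92 to 10.6), mostly through cluster 13 of WT control, and 1.44 points with each library clustered by itself.

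Genes of CD8 and killer cells were highest among KO control T-like cells relative to WT control: Cd8a (ENSMUSG00000053977), the CD8 alpha chain, was at 409 against 98.96 CPM (log2 ratio 2.05, 1.96 to 2.13). Ly6c2, a surface antigen of memory CD8 cells and monocytes, was at 1832 against 463 CPM (1.98, 1.95 to 2.02), and Klre1, a lectin-like killer receptor, at 166 against 41.6 CPM (2.00, 1.87 to 2.13). The lowest were Il1rl1, the IL-33 receptor, at 25.7 against 178.5 CPM (-2.80, -2.93 to -2.66), and Areg, the growth factor amphiregulin, at 207 against 1169 CPM (-2.50, -2.55 to -2.45). Cpm, a membrane carboxypeptidase, was at 24.3 against 127 CPM (-2.39, -2.53 to -2.24). At 1000 UMIs, 27.0% of KO control and 4.81% of WT control T-like cells had a Cd8a UMI, against 7.45% and 0% of macrophage-like cells, and 5.17% and 17.4% had a Foxp3 UMI, against 0.92% and 0.44%. Unthinned, the T-like shares were 41.1% and 11.98% for Cd8a and 10.4% and 41.7% for Foxp3, against 11.6% and 0.83%, and 1.62% and 5.00%, in macrophage-like cells. Thinning left out 1421 and 60 T-like and 284 and 11 macrophage-like cells, and the median depths were 2569 and 6020 UMIs in T-like and 1490 and 10117 UMIs in macrophage-like cells. Cluster 6, led by Ikzf2 and Tnfrsf4, held most T-like cells of WT control (1280 of 2054), and clusters 2 and 15 the largest numbers in KO control.

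Of 19 cytotoxic effector genes in T-like cells, 15 were higher in KO control and 1 lower (median 1.15, 1.12 to 1.17; percentile 100), with Ccl5 at 3636 against 1642 CPM, Nkg7 at 1531 against 496 CPM and Klrd1, the CD94 receptor, at 500 against 148 CPM; Gzmb stood at 924 against 1088 CPM. NK-like cells carry these genes too and took the larger share of KO control, where the list was also higher in macrophage-like cells. Of 14 regulatory T genes, 13 were lower and none higher (median -1.08, -1.22 to -1.04; percentile 0), with Ikzf2, encoding Helios, at 439 against 1172 CPM, the checkpoint gene Ctla4 at 383 against 795 CPM and Tnfrsf4 at 579 against 1189 CPM. The type I interferon median was 0.94 (0.86 to 0.97; percentile 100), with Isg15 at 781 against 406 CPM and Irf7, a regulator of interferon genes, at 260 against 114 CPM. Hypoxia and glycolysis genes (median -0.67, -0.75 to -0.62) and dissociation stress genes (-0.62, -0.68 to -0.60) were lower, with 11 of 19 and 10 of 17 members at least 1.5-fold lower. Interferon gamma response genes had a median of -0.33 (-0.52 to -0.24), MHC class II genes -0.42 (-0.63 to -0.30, or 0.70 with cells named by their own scores) and naive and memory genes -0.24 (-0.29 to -0.17). Exhaustion and checkpoint genes had -0.10 (-0.19 to 0.00), G2M phase genes -0.25 (-0.35 to -0.13), S phase genes 0.06 (-0.02 to 0.15), pyroptosis and inflammasome genes -0.20 (-0.29 to -0.10) and mitochondrially encoded genes -0.27 (-0.29 to -0.27). Extracellular matrix genes were lower for 14 of 15 members (median -2.26, -2.91 to -1.89), moving with the share of cluster 13. TMM scaling put the centre of T-like ratios at -0.18 in this pair, so values are shifted up by that amount relative to it: exhaustion and checkpoint genes then had a median of 0.08.

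Interferon genes also set apart the NK-like cells of KO control, most of them in the shallow cluster 19 where 138 of 146 WT control cells lay in cluster 7. Relative to WT control, Ifi27l2a was at 522 against 40.8 CPM (log2 ratio 3.68, 3.28 to 4.11) and Ly6a, the interferon-inducible antigen Sca-1, at 403 against 42.4 CPM (3.25, 2.86 to 3.67). The granzyme genes Gzmf, at 11.2 against 153 CPM (-3.77, -4.16 to -3.39), and Gzmd, at 50.7 against 228 CPM (-2.17, -2.40 to -1.94), were lowest. All 21 type I interferon genes were higher (median 1.64, 1.44 to 1.88). Medians were also positive for MHC class II (0.66, 0.39 to 1.05), regulatory T (0.32, 0.19 to 0.6) and exhaustion and checkpoint genes (0.3, 0.15 to 0.52). They were negative for naive and memory (-0.38, -0.44 to -0.15) and inflammatory macrophage genes (-0.54, -0.76 to 0.04). Unthinned, the T cell gene Cd3e was in 18.9% of KO control and 2.05% of WT control NK-like cells. Whether RNA from other cells, or mixed cells, gave part of the interferon difference was not tested. MHC class I genes had a median of 0.32 (0.25 to 0.36) with H2-K1 at 4253 against 2977 CPM, interferon gamma response genes 0.40 (0.28 to 0.79), cytotoxic effector genes -0.23 (-0.32 to -0.10; 1 of 19 members higher and 5 lower), and pyroptosis and inflammasome genes 0.10 (-0.20 to 0.29).

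Macrophage-like cells of KO control carried more interferon-induced RNA, Apoe and Cd74 than those of WT control. Apoe was at 7561 against 1920 CPM and Cd74 at 15743 against 8383 CPM; 4 of 10 MHC class II genes (median 0.48, 0.43 to 0.54) and 15 of 21 type I interferon genes (median 1.0, 0.91 to 1.21) were higher. Highest by the naming rule were Cd72, a C-type lectin, at 170.5 against 17.5 CPM (log2 ratio 3.29, 2.84 to 3.77), and the chemokines Ccl12 at 117 against 11.2 CPM (3.38, 2.82 to 4.00) and Ccl5 at 1397 against 184 CPM (2.93, 2.79 to 3.07). Next were Ly6a at 1222 against 182 CPM (2.75, 2.61 to 2.89), and Ms4a7 at 192 against 25.4 CPM (2.92, 2.54 to 3.32). Lowest were Ccl24, an eosinophil attractant, at 7.20 against 141 CPM (-4.30, -4.92 to -3.73), and fibronectin Fn1 at 216.5 against 1161 CPM (-2.42, -2.54 to -2.31). The aryl hydrocarbon receptor gene Ahr was at 42.0 against 154 CPM (-1.88, -2.15 to -1.60), the heat shock gene Hspa1b at 143 against 479 CPM (-1.75, -1.90 to -1.60), and Arg1 at 171 against 501.1 CPM (-1.55, -1.69 to -1.41).

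MHC class I genes in these cells had a median of 0.42 (0.36 to 0.50), interferon gamma response genes 0.46 (0.31 to 0.67) and chemokines 0.45 (0.32 to 0.57). Inflammatory genes had 0.07 (0.01 to 0.18) and lipid-laden genes 0.10 (0.05 to 0.34, or -0.14 with cells named by their own scores). Alternatively activated and resident-like genes had a median of -0.37 (-0.63 to -0.20), hypoxia and glycolysis genes -0.39 (-0.55 to -0.32), efferocytosis genes -0.36 (-0.48 to -0.14), mitochondrially encoded genes -0.48 (-0.51 to -0.44; percentile 0.2), and pyroptosis and inflammasome genes 0.01 (-0.16 to 0.11). With cells thinned to 1000 UMIs these 5 medians were -1.2, -0.72, -0.87, -0.79 and -0.34. Cytotoxic effector genes, which belong to NK and T cells, were higher for 15 of 17 members in macrophage-like cells of KO control (median 3.41, 2.93 to 3.68), with Nkg7 at 223 against 5.41 CPM. This moved with the NK-like share, and Ccl5 above stands beside it. Cluster 22 held 828 of the 1049 cells in KO control and cluster 9 held 202 of 240 in WT control.

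Dendritic cells could be compared in this pair. In cDC1-like cells, Ccl5 was at 837 against 5.30 CPM (log2 ratio 7.31, 6.26 to 8.63) and the T cell gene Cd3g at 178 against 9.0 CPM (4.30, 3.45 to 5.29), while Ifitm1 (54.9 against 397 CPM; -2.85, -3.35 to -2.39) and Hspa1b (102 against 400 CPM; -1.97, -2.34 to -1.63) were lower. Cytotoxic effector genes, too, were higher in the dendritic classes, for 10 of 11 members in cDC1-like cells (median 3.64, 2.71 to 4.11) and 14 of 14 in cDC2-like cells (1.99, 1.77 to 2.42), as in macrophage-like cells. Mitochondrially encoded genes had medians of -0.49 (-0.55 to -0.43) and -0.93 (-0.99 to -0.87). Median depths were 1837.5 against 19012 UMIs in cDC1-like and 1192 against 15773.5 UMIs in cDC2-like cells. In cDC2-like cells, Ly6c2 (765 against 60.9 CPM; 3.65, 3.31 to 4.01) and Ly6a (1268 against 167 CPM; 2.92, 2.71 to 3.14) were higher, and the macrophage elastase Mmp12 (4.90 against 236 CPM; -5.60, -7.48 to -4.23) and the chemokine Ccl17 (52.3 against 385 CPM; -2.88, -3.37 to -2.43) were lower. In the KO pair, migratory dendritic cells of the treated library had Cxcl1, a neutrophil attractant, at 63 UMIs (224 CPM) against 0 (at least 52.4-fold higher) and Gnl2 at 199 against 37.0 CPM (2.43, 1.73 to 3.16), with Ccl17 at 0 UMIs against 114 (at least 15.2-fold lower) and Ccl4 at 39.0 against 334 CPM (-3.10, -4.12 to -2.23). Cytotoxic effector genes were lower there for 11 of 15 members (median -1.27, -1.56 to -0.68, or -0.07 with cells named by their own scores) and mitochondrially encoded genes for 5 of 8 (-0.71, -0.84 to -0.57). B-like cells of that pair had Gzmg at 152 UMIs against 0 (at least 18.6-fold higher) and Ramp3 at 95 against 0 (at least 11.6-fold higher), with Prg2 at 1 UMI against 28 (-6.25, -11.6 to -3.66) and the immunoglobulin joining chain Jchain at 775 against 7164 CPM (-3.21, -3.35 to -3.07). The cells that hold the Gzmg, Ramp3 and Prg2 UMIs were not counted, so few cells may give these ratios. This class pools B and plasma cells. Cluster 24 held 29 of 453 cells in KO treated and 14 of 78 in KO control, and globin made up 14.3% and 3.77% of the UMIs of the whole class.

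The unnamed cluster 11, whose leading genes include Mgp and Sparc, also had enough cells in WT control and KO control (89 and 324). Its KO control cells had higher proliferation and antigen-presentation RNA: 15 of 17 G2M phase genes (median log2 ratio 1.44, 1.11 to 1.75), 9 of 17 S phase genes (0.81, 0.35 to 1.05), 15 of 16 type I interferon genes (1.82, 1.38 to 2.17) and 12 of 15 MHC class I genes (1.05, 0.83 to 1.29) were higher. RNA of leukocytes was higher with them, in 8 of 8 cytotoxic effector genes (2.06, 1.58 to 2.61) and 5 of 5 MHC class II genes (2.69, 2.17 to 3.36). So it was in 7 of 8 exhaustion and checkpoint genes (1.37, 0.91 to 2.28) and 4 of 5 regulatory T genes (2.21, 1.13 to 2.99, but -0.27 with cells thinned to 1000 UMIs). Top2a, a mitotic topoisomerase, was at 128 against 37.1 CPM and H2-K1 at 2155 against 709 CPM. Extracellular matrix genes were lower for 12 of 17 members (median -1.0, -1.45 to -0.83) and hypoxia and glycolysis genes for 16 of 19 (-0.96, -1.33 to -0.77). Genes of MAPK output, the transcripts that ERK signaling induces, had a median of -0.14 (-0.41 to 0.22), and dissociation stress genes -0.07 (-0.21 to 0.14). With cells thinned to 1000 UMIs these medians were -0.85 and -0.48, and that of extracellular matrix genes -1.77. Lgals7 (444 against 13.1 CPM; 5.09, 3.95 to 6.54) and Hspa1a (163 against 8.70 CPM; 4.22, 2.84 to 6.12) were highest, and Ctgf (13.9 against 321 CPM; -4.53, -5.37 to -3.78) and Flna (10.4 against 207 CPM; -4.31, -5.32 to -3.44) lowest.

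Cluster 11 held other cells in KO treated. Rgs5, a pericyte gene, gave 253 UMIs there against 2 in KO control (log2 ratio 9.82, 7.95 to 12.9), Igfbp3 gave 433 UMIs against 0 (at least 1031-fold higher), Pla2g7 gave 0 against 381 (at least 17.8-fold lower), and Lgals7 1 against 512 (-6.16, -11.5 to -3.68). The list medians of KO treated over KO control in this cluster were 0.77 for MAPK output (0.17 to 1.06), -2.31 for G2M phase (-2.40 to -1.75), -1.49 for S phase (-1.60 to -0.90) and -0.44 for type I interferon (-0.79 to 0.03). They were 0.06 for MHC class I (-0.19 to 0.14), 2.86 for extracellular matrix (2.64 to 3.08), 2.51 for dissociation stress (2.42 to 2.72) and -1.25 for hypoxia and glycolysis (-1.56 to -0.75). TMM scaling put the centre of these ratios at 0.61, so that the MAPK output median became 0.16 and the MHC class I median -0.55. In T-like cells the MAPK output median was -0.51 (-0.67 to -0.37) for WT treated over WT control and -0.30 (-0.53 to -0.12) for KO treated over KO control. In the KO pair it was -0.71 (-1.12 to -0.51) in macrophage-like, -1.53 (-1.90 to -0.33, 5 members) in B-like and 0.58 (0.17 to 0.74) in NK-like cells. Without drug, T-like cells had -0.57 (-0.63 to -0.43) for KO control over WT control. In cluster 1, Pim1 (1514 against 395 CPM; 1.94, 1.57 to 2.31) and Cdk11b (1026 against 267 CPM; 1.94, 1.49 to 2.39) were higher in KO treated than KO control, and Ccl4 (0 UMIs against 67; at least 5.5-fold lower) and Hspa1a (3 UMIs against 131; -3.44, -5.74 to -1.86) were lower. Cluster 1 of KO control over WT control had Ifi27l2a (690 against 210.5 CPM; 1.71, 1.23 to 2.23) and Ccl4 (208 against 50.1 CPM; 2.06, 1.09 to 3.18) higher, and Slc24a1 (12.4 against 100.2 CPM; -3.01, -5.02 to -1.43) and Fosb (364 against 1068 CPM; -1.55, -1.89 to -1.22) lower. Its median mitochondrial share was 9.71%, 7.43% and 7.5% in WT control, KO control and KO treated. Globin made up 22.49%, 20.3% and 2.99% of its UMIs in the same order.

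The fourth comparison asks whether tumors of knockout cells differed under drug. KO treated held relatively more B-like and stromal cells and fewer T-like cells than WT treated, and its T-like cells carried less regulatory T and checkpoint RNA and more Il17a. T-like cells were 66.1% of immune cells against 83.1% (-17.0 points, -20.2 to -13.5), and B-like cells 11.1% against 1.15% (9.95 points, 8.43 to 11.1; 3.7 points with cells named by their own scores and 14.93 with each library clustered by itself). Monocyte/macrophage-like cells were 5.02% against 3.12% (205 of 4082 and 19 of 609; 1.90 points, 0.09 to 3.22, or 3.65 with the stricter filter and 3.89 with each library clustered by itself), and NK-like cells 4.02% against 4.27% (-0.25 points, -2.24 to 1.24). Il17a was at 252 against 16.1 CPM in T-like cells (log2 ratio 3.97, 3.62 to 4.33), from 69 of 2697 and 4 of 506 cells.

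The immune share of all cells was lower in KO treated by -12.2 points (-14.0 to -9.87; -5.99 with innate lymphoid markers apart from T and -26.55 with each library clustered by itself), with fibroblast-like cells at 4.85% against 0 of 644. The value of -5.99 arises because T-like cluster 8 no longer counted as immune under that setting. Endothelial-like cells were 5.27% against 3 of 644, and skeletal muscle-like cells 3.25% against 2 of 644. The endothelial-like difference of 4.80 points was 2.0 points with cells named by their own scores. The muscle-like difference of 2.94 points was 0.24 points with each library clustered by itself. Dendritic cells were 3.94% against 2.30% (1.65 points, 0.02 to 2.77). Neutrophils were 9.80% against 6.08% (3.72 points, 1.37 to 5.62), a difference that turned to -3.44 points with the stricter filter, to -3.90 at the finer clustering resolution and to -1.07 with cells named by their own scores. Median depth was 1143 UMIs in KO treated and 7711.5 in WT treated, the widest gap of the 4 pairs, and the T difference was -10.2 points among cells of at least 2000 UMIs and -5.74 with cells named by their own scores.

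In T-like cells, Ifitm1 (322 against 80.1 CPM; log2 ratio 2.01, 1.85 to 2.17) and Cd7 (119 against 37.5 CPM; 1.67, 1.42 to 1.92) were also highest in KO treated. Il1rl1 (29.5 against 177 CPM; -2.59, -2.81 to -2.36), the proenkephalin gene Penk (27.0 against 134 CPM; -2.31, -2.56 to -2.08) and Hspa1a (34.5 against 163 CPM; -2.24, -2.46 to -2.03) were lowest. Of 13 regulatory T genes, 11 were lower and none higher (median -1.04, -1.17 to -0.98), with Ikzf2 at 305 against 813 CPM and Il2ra, the IL-2 receptor alpha chain, at 119 against 409 CPM. Of 14 exhaustion and checkpoint genes, 9 were lower and none higher (median -0.80, -0.85 to -0.66), with Ctla4 at 375 against 772 CPM and Icos at 439 against 731 CPM. At 1000 UMIs, 5.01% of KO treated and 13.5% of WT treated T-like cells had a Foxp3 UMI (7.27% and 32.4% unthinned), against 3.20% and 0% of macrophage-like cells (4.39% and 0% unthinned). A Cd8a UMI was found in 12.8% and 12.4% (18.8% and 29.2% unthinned), against 2.40% and 0% (3.90% and 0%). An Il17a UMI was found in 2.98% and 0.41% (2.56% and 0.79% unthinned), against 0% of macrophage-like cells in both. Thinning left out 1119 and 16 T-like cells and 80 and 0 macrophage-like cells, and the median depths were 1195 and 8105.5 UMIs in T-like and 1297 and 14691 UMIs in macrophage-like cells. Cluster 2 held most T-like cells of KO treated and cluster 6 the largest number in WT treated (206 of 506).

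The type I interferon list had a median of 0.20 between the treated libraries (0.04 to 0.29, or 0.50 with cells thinned to 1000 UMIs), with 4 members higher, 4 lower and 12 within 1.5-fold. Within single clusters its median went from -0.19 in cluster 8 to 0.84 in cluster 5. Cytotoxic effector genes had a median of -0.43 (-0.51 to -0.31), which was -0.01 with cells thinned to 1000 UMIs. Interferon gamma response genes had -0.56 (-0.67 to -0.47), hypoxia and glycolysis genes -0.55 (-0.66 to -0.38), and dissociation stress genes -0.48 (-0.52 to -0.41). Naive and memory genes had a median of 0.26 (0.14 to 0.36) with S1pr1 at 352 against 156 CPM, and MHC class II genes 0.29 (0.14 to 0.79), a value that was -0.24 with 5% of the library profile subtracted, -0.06 with each library clustered by itself and 2.65 with cells named by their own scores. Mitochondrially encoded genes had a median of -0.63 (-0.66 to -0.61; percentile 0.1), with 4 of 8 lower. S phase genes had 0.13 (0.03 to 0.36), G2M phase genes 0.08 (-0.16 to 0.48), and pyroptosis and inflammasome genes 0.07 (-0.11 to 0.15). Extracellular matrix genes were higher for 5 of 6 members (median 3.39, 3.11 to 3.73), beside the fibroblast-like cells of the library, and the median was -0.80 with each library clustered by itself. TMM scaling put the centre of T-like ratios in this pair at -0.24; relative to it the interferon median was 0.43 and the regulatory T median -0.81.

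The drug-to-control ratios of the 2 genotypes are compared for 3 T cell lists that were picked after all lists had been seen. Other lists differed by more than the first of them, among them MHC class II (0.98), chemokines (0.98) and efferocytosis (0.65). KO minus WT, the difference in median log2 ratio was -0.52 for the type I interferon list (-0.75 to -0.30), both ratios being negative. It was -1.36 for cytotoxic effector genes (-1.48 to -1.22), from 0.35 in WT and -1.01 in KO, and 3.95 for extracellular matrix genes (3.11 to 4.67), from -2.17 and 1.78. Each ratio rests on 1 library per group, so the spread of such a difference between tumors is unknown.

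**Figure D3:**
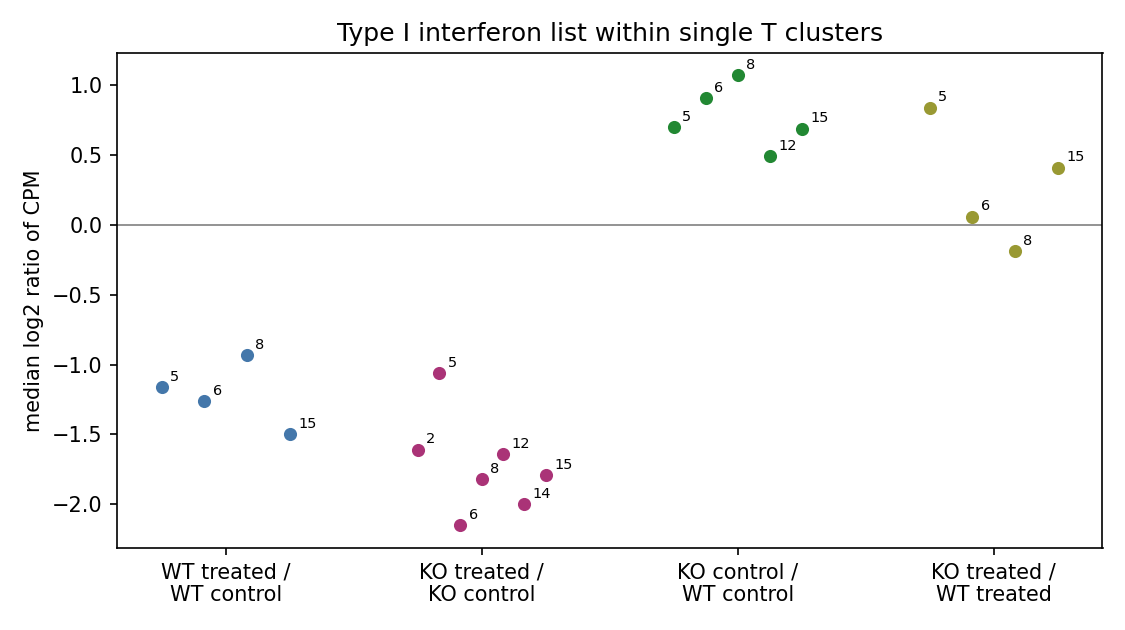
Median log2 ratio of CPM for the type I interferon list within single T-like clusters that hold at least 50 cells in both libraries of a pair. Each point is 1 cluster, numbered beside it; the highest cluster lies at -0.93 in the WT drug pair and at -1.06 in the KO drug pair.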

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

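The thinned test of the interferon list, the tests of blood, the limit of 2000 UMIs and the setting with no minimum score were chosen only after the result or the data were seen; the other tests below were set before.

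The drug went with opposite directions in the 2 genotypes, with both intervals clear of 0, for 4 of the reported results, and the difference was not tested in any of them. The immune share of all cells differed by 9.81 points in WT and by -11.56 points in KO. Other cell groups moved with it. Clusters 13 and 11 took 7.78% and 2.77% of WT control and 0 cells of WT treated. Fibroblast-like, endothelial-like and muscle-like cells together took 13.37% of KO treated and 0.67% of KO control. The cytotoxic effector median in T-like cells was 0.35 in WT and -1.01 in KO. The extracellular matrix median in T-like cells was -2.17 in WT and 1.78 in KO, from genes at no more than 13.1 CPM in the WT libraries, where cluster 13 was present only without drug. The chemokine median in T-like cells was -0.73 in WT (0.13 with each library clustered by itself) and 0.25 in KO (-2.5 with 5% of the library profile subtracted).

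Type I interferon RNA was lower in T-like cells of both treated libraries. Another mix of T subsets as the whole cause is argued against by the medians within single T clusters, -1.21 over 4 clusters in WT (highest -0.93) and -1.79 over 7 in KO (highest -1.06). With cells thinned to 1000 UMIs, the medians were -1.84 in WT and -2.28 in KO. This argues against the unequal weight of deep and shallow cells as the whole cause. Thinning leaves the expected CPM of a cell and its free RNA as they were, so it cannot decide on other effects of depth. A biological effect of the drug may account for it, and so might any other difference between the single libraries, which the design cannot separate.

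NK-like cells took 4.38 times the share in KO control that they took in WT control. Most of the excess lay in cluster 19 (1537 cells against 8), while cluster 7 held 676 and 138. Cluster 19 lay mostly in KO control, so it may be that library rather than a type. Among immune cells of at least 2000 UMIs the ratio was 3.17 (828 of 4402 against 141 of 2374), which argues against shallow barcodes as the whole cause. Free NK RNA in cells of other types, or mixed cells, stays open: Ncr1 was found in 30.6 times the share of NK-like as of T-like cells in KO control, but it is a gene the name rests on, so this decides nothing. The T cell gene Cd3e was in 12.2% of NK-like cells of KO control and 1.38% of WT control at 1000 UMIs. In macrophage-like cells of these libraries it was in 8.89% and 0.87%. The genotype of the injected cells may account for the higher NK-like share, as might the dissociation, sort or sampling of that pool, which were not tested.

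Endothelial-like, muscle-like and B-like cells lay mostly in KO treated, and so did fibroblast-like cells unless cells were named by their own scores (6.88% of WT control against 5.03%) or cluster 13 took that name (7.9% of WT control with no minimum score). Among cells of at least 2000 UMIs their share was 12.96 times that of KO control (233 of 1351 against 61 of 4584), which argues against shallow barcodes as the whole cause of the difference between the KO libraries. Fibroblast-like, endothelial-like and muscle-like cells, which blood lacks, took 19.99 times the share (662 of 4953 against 67 of 10022). This ratio restates the pattern, so as a test of blood carried into the sample it decides nothing. For B-like cells, which blood holds, that source stays open: their share was 11.75 times and the globin share of UMIs 3.81 times that of KO control. More skin and muscle around smaller tumors could give this, and so could the drug or the genotype; none of these was tested.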

How the results depend on the processing

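The settings with innate lymphoid markers apart from T and with cells of at least 2000 UMIs were chosen only after the result was seen. No paired analysis was possible because each group has 1 library. The depth gap bears on shares: 2895 and 2132 kept cells of KO control and KO treated, against 158 and 27 of the WT libraries, hold under 1000 UMIs. Planned results in a melanoma class have no value under any setting, since no cluster took that name.

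Over all alternatives, 12 results on the immune, macrophage and T shares gave 140 values, of which 82 stayed within the counting interval, 56 moved with the same direction and 2 reversed, that is, changed sign from a value clear of 0. Of 324 values of 28 other shares, 248 stayed, 73 moved and 3 reversed; 7 of those that moved and 8 that stayed also changed sign, from a value whose interval held 0. Of 1504 values of 134 list medians, 1216 stayed, 283 moved and 5 reversed; 30 of those that moved and 24 that stayed also changed sign, from a median under 1.5-fold. For the difference between genotypes in T lists, 34 of 39 values stayed and 5 moved. The cause was not tested for any value below, which are given as treated minus control in WT or KO, or KO minus WT in control or treated, in points unless a median is named.

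With the looser filter the immune difference was -9.7 in KO, 11.23 in control and -7.42 in treated, and the T difference 8.33 in KO and -17.47 in control. With the stricter filter the immune difference was -18.23 in KO, 7.32 in control and -20.23 in treated, the macrophage difference -4.96 in KO and 3.65 in treated, the T difference 15.64 in KO and -10.12 in treated, and the neutrophil difference in treated reversed to -3.44. With doublets kept the immune difference was -9.23 in KO, the macrophage difference -8.78 in WT and reversed to -0.93 in control, the T difference -18.09 in control, and the genotype difference in the cytotoxic list -1.16. At resolution 0.5 the immune difference was 7.62 in control and -14.96 in treated. At resolution 2.0 it was -19.0 in KO and -18.15 in treated, the macrophage difference was -4.9 in KO, the T difference 13.35 in KO, -17.2 in control and -12.13 in treated, the neutrophil difference in treated reversed to -3.9, and the genotype difference in the cytotoxic list was -1.21.

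With each library clustered separately the immune difference was -16.79 in KO, 1.44 in control and -26.55 in treated, and the macrophage difference -4.1 in KO and 3.89 in treated. The T difference there reversed to -3.92 in KO and was -16.5 in control and -28.9 in treated, and in T-like cells the matrix median reversed to -0.8 in treated and the chemokine median to 0.13 in WT. With cells named by their own scores the inflammatory macrophage median in T-like cells reversed to 1.31 in treated, the immune difference was -9.83 in KO and 6.71 in control, and the macrophage difference -9.49 in KO and 5.61 in control. The T difference there was 11.06 in WT, 13.56 in KO, -8.24 in control and -5.74 in treated, and the neutrophil difference in treated reversed to -1.07. With innate lymphoid markers apart from T the immune difference was 6.41 in WT, -12.97 in KO, 13.39 in control and -5.99 in treated. These values arise because T-like cluster 8 no longer counted as immune under that setting. It held 240, 70, 330 and 233 cells of WT control, WT treated, KO control and KO treated.

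With cells thinned to 1000 UMIs the immune difference was -9.45 in KO, 6.18 in control and -14.34 in treated, the T difference -17.37 in control, the G2M median in T-like cells reversed to 0.17 in KO, the regulatory T median in cluster 11 to -0.27 in control, and the genotype differences were -1.67 in the cytotoxic and 5.44 in the matrix list. With cells of at least 2000 UMIs the immune difference was -8.39 in KO and -9.37 in treated, the macrophage difference -4.53 in KO and 0.41 in control, and the T difference -11.11 in control and -10.16 in treated. With all kept cells as denominator the T difference was 14.66 in WT, 2.48 in KO, -11.93 in control and -24.12 in treated. With 5% of the library profile subtracted the genotype difference in the matrix list was 2.76.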

Other observations

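The test below was set before the result was seen, but the rule that reads it was changed after, and the setting with no minimum score and the removal of chromosome 15 were chosen only after.

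Clusters 11 and 13 took no name and may hold cells of the injected line. Cluster 13 scored nearest to fibroblast (0.245, with 4 markers), below the 0.3 needed, and took that name with no minimum score. Over 19 autosomes, the deviations of cluster 13 in WT control correlated with those of cluster 11 in KO control (0.65, 4445 genes) and WT control (0.67, 2496 genes), against -0.07 for fibroblast-like (1985 genes) and 0.19 for endothelial-like cells (2000 genes) of KO treated, an excess of 0.46. Chromosome 15 carries much of this: without it the values for cluster 11 were 0.45 and 0.1. Its deviation was 0.53 in cluster 13 of WT control, and 0.4 and 0.26 in cluster 11 of WT control and KO control. In fibroblast-like and endothelial-like cells of KO treated it was -0.02 and 0.06. A cell type shared by these clusters, such as another kind of fibroblast, might also give a correlation, which was not tested. Cluster 13 of WT control held 66 UMIs of Cdkn2a (9.9 CPM), a gene the YUMM1.7 line has lost. That loss is known from outside these data, and a 3' tag can lie outside a lost part. Sox9, of the neural crest list, was at 289.5 CPM in cluster 13 of WT control and 43.1 CPM in fibroblast-like cells of KO treated. The melanoma marker Sox10 gave 0 UMIs over all kept cells of WT control. The origin of the cells of clusters 11 and 13 stays open.

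The male-linked RNA Ddx3y was at 91.6, 117, 83.9 and 89.9 CPM in WT control, WT treated, KO control and KO treated, and the female-linked Xist gave 0, 0, 6 and 0 UMIs. Globin genes made up 0.75%, 0.27%, 1.90% and 7.23% of the UMIs of the same libraries.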
